A study of Ovis aries with 8 samples.

How the data were processed

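The table deposited by the authors holds TPM, a measure of transcript abundance corrected for transcript length, for 28475 genes in 8 libraries, which were estimated with Salmon per the submitters' processing notes. Its version and the genome build were not given in the sources used here. Each column summed to 1000000 TPM. By symbol, 28429 of the gene names were found in a RefSeq annotation of the sheep genome, and the other 46 ended in "_1". Mitochondrially encoded genes in the table numbered 0. Read counts were not used here, so tests that model counts were not applied.

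Values were transformed to log2(TPM + 1), with a pseudocount of 1. Genes with at least 1 TPM in at least 2 libraries were tested, which left 14779. Linear models were fitted with limma 3.58.1 in R 4.3.3, with moderated variances that follow a trend in mean level, and two-sided p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. State was tested with 4 naive-like against 4 primed libraries, and the other comparisons were contrasts in a fit of 4 groups with 2 libraries each. Errors of log2 changes are standard errors from limma, and errors of TPM are standard deviations between libraries. Of genes tested for state, the libraries of the groups did not overlap in 7046, where chance gives 2.86%.

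Gene lists were tested with camera at a preset correlation between genes of 0.01, again with an estimated correlation, and with fry. Calls of lists refer to the preset correlation. With an estimated correlation, camera in limma called 0 lists in each comparison, and 6 lists for state, 6 for MEFs, 2 for lines and 6 for feeder-free naive-like against primed cells had an unadjusted p under 0.05. For state, the estimated correlation was below the preset in the core pluripotency (−0.00948), Nodal and Activin (−0.0144) and epithelial (−0.00224) lists. Their calls ended all the same. Correlation between genes therefore does not explain the loss of those calls, and its cause was not tested. With camera, 27 of 29 lists held at least 3 tested genes. Tests with fry ask whether the genes of a list move on balance in 1 direction and do not compare them with other genes. Tests of lists were planned for state, for MEFs against feeder-free and between the lines, and those without a described result for one of these did not pass in it. Lists for feeder-free naive-like against primed cells were added after seeing the data, and of 12 called there, the 10 also called for state are given as a group. Apart from these, the comparisons, lists and alternatives were set before the data were examined, as was the rule for naming genes. A list of targets of the aryl hydrocarbon receptor and rescaling without ribosomal RNA genes were chosen after seeing the data.

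Genes were named by rule. In each comparison it took the 10 largest rises and 10 largest falls among genes with an adjusted p under 0.05, a mean of at least 5 TPM, a gene symbol and no overlap between the groups compared. It also took up to 4 tested members of each list with the smallest adjusted p, and any member of the core, naive and primed pluripotency lists. Some genes that the rule or a small count would name are not reported here. Genes outside the rule are marked in the text as named after their values were seen.

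The procedure was tested on simulated libraries with 14779 genes, of which 67, 67 and 66 were changed by 1.5-fold, 2-fold and 4-fold. For state it recovered 83.6%, 92.5% and 95.5% of these with 8 false calls, and for feeder-free naive-like against primed libraries 62.7%, 85.1% and 95.5% with 6. For MEFs against feeder-free it recovered 53.7%, 79.1% and 93.9% with 5 false calls, and for the primed lines 49.2%, 83.6% and 93.9% with 7. Each gene was drawn independently around its mean with its spread within groups, without line or feeder differences. The figures for state therefore leave out the spread between subgroups that the real libraries hold. Fewer genes were changed than passed in the real comparisons (762 to 8331). The adjusted threshold depends on that number, so the rates need not carry over to the real fits. Of 20 simulated lists with 15 genes each, 5 were shifted. For state, for MEFs and between the lines, camera recovered 5 with 0 false calls, at the preset and at the estimated correlation alike. Because the simulated genes were independent, this cannot test the preset correlation for real lists, whose genes may move together. Lists for feeder-free naive-like against primed cells were not simulated.

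Alternatives changed a single choice at a time. They were a pseudocount of 0.1 or 5, no filter or a mean of at least 5 TPM, median-ratio scaling, quantile normalization, rescaling without ribosomal protein genes, no variance trend, an adjusted p under 0.01, a change of at least 2-fold, the replicate number as a block, the subgroup as a random block, means of subgroups, a fit with all 4 groups or with the groups compared alone, a single primed line, feeder-free cells alone, and leaving out each library in turn. A library left out leaves its group with 1 library, which is then assumed to vary like the other groups.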

Results

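RNA sequencing was done on 8 libraries of polyadenylated RNA from sheep embryonic stem cells, which are pluripotent cells derived from the inner cell mass of the blastocyst. They fell into 4 groups of 2 libraries. The first 2 groups were primed cells of line A and of line B, grown without feeder cells at passage 10 in medium with 20 ng/mL Activin A, 20 ng/mL bFGF, 3 µM of the tankyrase inhibitor endo-IWR-1 and 1% BSA. The other 2 groups were naive-like cells at passage 12, grown without feeder cells or on mouse embryonic fibroblasts (MEFs, which serve as a supporting layer). Naive-like medium held inhibitors of MEK (PD0325901, 1 µM), tankyrase (XAV-939, 2 µM), protein kinase C (Go6983, 2 µM) and SRC (CGP77675, 1.2 µM), with Activin A and LIF at 20 ng/mL each and ascorbic acid at 50 µg/mL. Cultures were kept at 37 °C and 5% CO2. Medium and passage changed together with the state of the cells, and the line from which the naive-like cells came was not given in the sources used here.

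The deposited table listed 28475 genes in TPM, a transcript abundance scaled to the same total in each library, and 13294 to 13664 of them were at 1 TPM or more in a library. Labels gave about 20 M paired-end reads per library. Depth behind each value is unknown because TPM do not hold counts. Gene symbols serve as identifiers, and the genome build of the quantification was not given in the sources used here, so no positions are reported. Whether the 2 libraries of a group came from separate cultures was not stated, so the p-values measure only the spread between these libraries. Across genes, log2(TPM + 1) correlated at 0.982 to 0.985 between the libraries of a group, at 0.969 to 0.980 between groups of the same state and at 0.922 to 0.933 between states. Genes are not independent replicates in these correlations. The first principal component held 62.6% of the variance and the second 11.02%.

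**Figure D1:**
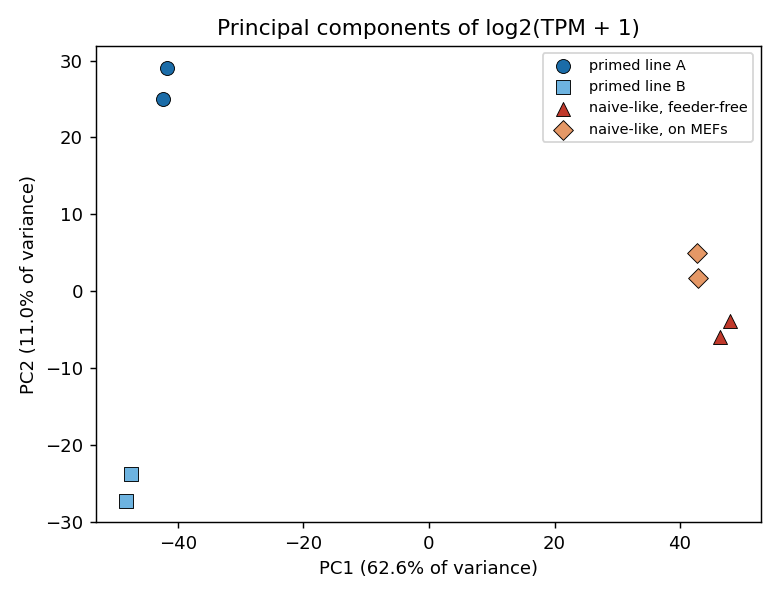
Scores of the 8 libraries on the first 2 principal components of log2(TPM + 1), with 62.6% of the variance on the horizontal axis and 11.02% on the vertical axis. Points are libraries, coloured by group, and the primed and naive-like libraries lie apart along the horizontal axis.

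The comparison of state asked how the 4 naive-like libraries differed from the 4 primed libraries. CYP1A1, a cytochrome P450 enzyme induced through the aryl hydrocarbon receptor, was at 670 ± 136 TPM (SD, n = 4) in naive-like cells and at 2.42 ± 0.373 TPM (n = 4) in primed cells. CLDN7, a tight junction protein, stood at 269 ± 30.4 TPM against 4.02 ± 1.29 TPM, and GSC, a homeobox gene of the embryonic organizer, at 61.7 ± 12.1 TPM against 1.03 ± 0.325 TPM. In the other direction, DLK1, an imprinted gene for a membrane protein related to Notch ligands, was at 1.81 ± 0.396 TPM in naive-like cells and at 121 ± 20.5 TPM in primed cells. CNTFR, the receptor of ciliary neurotrophic factor, was at 1.29 ± 0.261 TPM against 91.2 ± 11.4 TPM. Of 14779 genes tested with limma, 7493 passed at an adjusted p under 0.05, of which 4233 rose and 3260 fell in naive-like cells. With median-ratio scaling 3635 rose and 3903 fell, and 3776 and 3641 after rescaling without ribosomal RNA genes, chosen after seeing the data, so the balance of directions depends on scaling. With the libraries of a group averaged, 4023 genes passed, and 5848 with the group as a random block. Of the 4233 rises and 3260 falls, 706 and 889 were at least 2-fold. These folds are on the scale of log2(TPM + 1), which understates changes in genes with low TPM.

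CYP1A1 rose by 7.60 ± 0.141 (log2, SE), CLDN7 by 5.79 ± 0.190, the basement membrane collagen COL4A4 by 5.40 ± 0.10 and GSC by 4.94 ± 0.162. Rises were also found in AP1M2 (4.70 ± 0.0998), ESRP1 (4.59 ± 0.0990), CLIC6 (4.46 ± 0.185), EOMES (4.45 ± 0.114), PTPRR (4.30 ± 0.137) and NODAL. NODAL, a ligand of the TGF-beta family, was listed at 0 in 2 primed libraries and at 0.0535 and 0.108 TPM in the others, against 32.7 and 33.8 TPM in feeder-free and 19.6 and 18.1 TPM in MEF libraries. Falls taken by the naming rule (a mean of at least 5 TPM, a gene symbol and no overlap) were in DLK1 (−5.43 ± 0.139), CNTFR (−5.33 ± 0.116), IGDCC3 (−5.31 ± 0.130) and ANKRD46 (−5.31 ± 0.129), then in CAPN6 and NDN, and then in DUSP4 (−4.94 ± 0.170), SP8 (−4.78 ± 0.108), OLFML3 (−4.73 ± 0.173) and LHX2 (−4.53 ± 0.126). CAPN6 was at 47.8 to 50.8 TPM in primed libraries, was listed at 0 in feeder-free replicate 2, and was at 0.118, 0.737 and 0.806 TPM in the other naive-like libraries. NDN, an imprinted gene, was at 30.6 to 59.7 TPM in primed libraries, was also listed at 0 in feeder-free replicate 2, and was at 0.0531, 0.529 and 0.510 TPM in the other naive-like libraries. The share of TPM in 18 ribosomal RNA genes was 2.31 ± 0.959% in naive-like and 5.42 ± 0.821% in primed libraries. Of 20 fibroblast genes tested, 7 fell and 13 did not pass, as they did adjusted over the list alone (camera, adjusted p = 0.0855, and adjusted p = 0.606 with an estimated correlation).

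POU5F1, the core factor of pluripotent cells, was at 1607 ± 84.1 TPM in naive-like cells and at 638 ± 23.2 TPM in primed cells, a rise of 1.33 ± 0.0495. NANOG rose by 2.91 ± 0.193, from 12.3 ± 3.03 to 98.8 ± 25.2 TPM, and PRDM14 by 2.66 ± 0.0777, while SOX2 stood at 313 ± 13.7 against 308 ± 17.4 TPM (adjusted p = 0.739). Of 14 core pluripotency genes tested, 7 rose, 3 fell and 4 did not pass, with 7 and 3 adjusted over the list alone. The list as a whole was higher (camera, adjusted p = 0.0182). That call was lost with an estimated correlation (camera, adjusted p = 0.163), although the estimate of −0.00948 was below the preset 0.01. The other rises were in ZSCAN10 (1.91 ± 0.108), FOXD3 (1.20 ± 0.0860), TRIM71 (0.44 ± 0.0537) and GDF3, which was listed at 0 in all 4 primed libraries and was at 9.42 and 14.2 TPM in feeder-free and 5.28 and 8.23 TPM in MEF libraries. LIN28A (−0.27 ± 0.0811), LIN28B (−0.40 ± 0.108) and DPPA2 (−1.17 ± 0.350) fell. Without line A replicate 2 or feeder-free replicate 2, the adjusted p of DPPA2 was 0.0519 to 0.0540. SALL4 (0.24 ± 0.104, adjusted p = 0.0802), DPPA4 (0.32 ± 0.243) and UTF1 (−0.01 ± 0.108) did not pass along with SOX2.

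Naive pluripotency genes split, with 3 of 5 tested rising and 2 falling, 3 and 2 adjusted over the list alone (camera, adjusted p = 0.425, and adjusted p = 0.606 with an estimated correlation). KLF5 rose by 2.21 ± 0.0887, from 11.1 ± 0.970 to 55.3 ± 5.20 TPM, KLF4 by 1.83 ± 0.188 to 5.39 ± 1.48 TPM and TFCP2L1 by 1.74 ± 0.142 to 3.05 ± 0.315 TPM. SUSD2, a surface marker of human naive cells, fell by 1.20 ± 0.112. GBX2 was at 0.613, 0.282, 2.24 and 2.10 TPM in primed libraries, and in naive-like libraries it was listed at 0 except at 0.0384 TPM in MEF replicate 1. Of the 22 names on that list, 19 were in the table. Those of the 19 that were not among the 5 tested did not reach 1 TPM in 2 libraries, so the list rests on few of its genes. Primed pluripotency genes also went both ways, with 7 of 23 rising, 12 falling and 4 not passing, or 8 and 12 adjusted over the list alone (camera, adjusted p = 0.223, and adjusted p = 0.606 with an estimated correlation). The surface protein CD24 rose by 2.29 ± 0.0498, the de novo DNA methyltransferase DNMT3B by 2.05 ± 0.0698 to 418 ± 28.6 TPM, TCF7L1 by 1.18 ± 0.0598, OTX2 by 0.75 ± 0.0715 and ZIC2 by 0.41 ± 0.0650. Falls were found in CDH2 (−3.44 ± 0.159), DUSP6 (−2.56 ± 0.309), DNMT3A (−1.15 ± 0.0832) and FGF5 (−1.08 ± 0.130). SOX3 was at 6.46 to 8.98 TPM in primed libraries, at 0.139 and 0.0368 TPM in feeder-free libraries, and was listed at 0 in both MEF libraries.

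**Figure D2:**
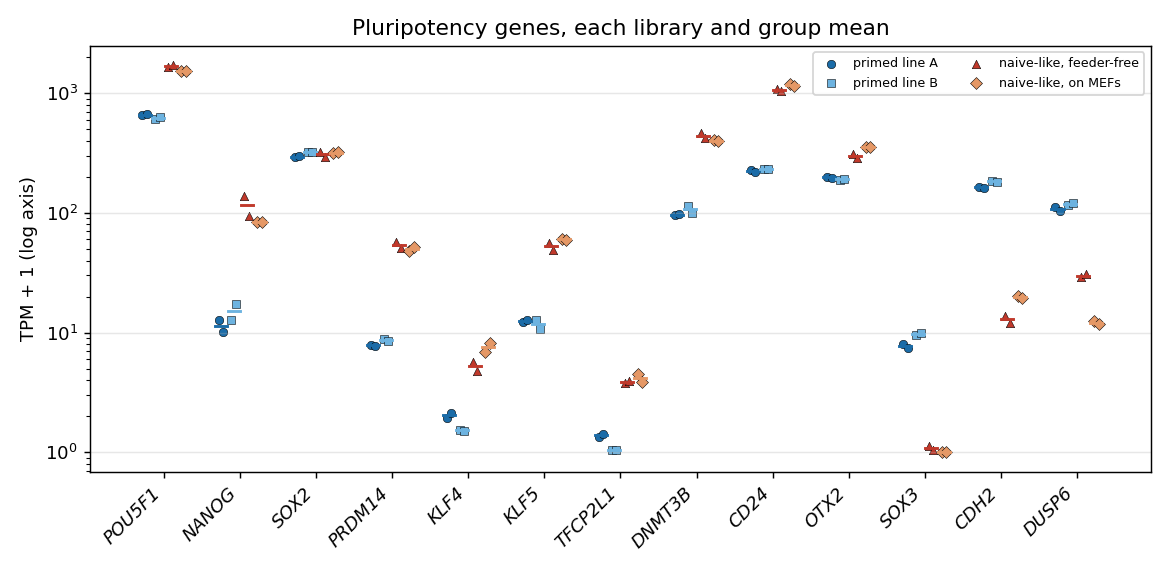
TPM + 1 of 13 pluripotency genes in each library on a log axis, with points for libraries and bars for the mean of each group. POU5F1, NANOG and DNMT3B lie higher in the 4 naive-like libraries, CDH2 and SOX3 lie higher in the 4 primed libraries, and SOX2 overlaps.

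Targets of FGF, MEK and ERK signalling were lower in naive-like cells, whose medium holds a MEK inhibitor and no added bFGF: 14 of 21 tested fell, 3 rose and 4 did not pass, with 3 rises and 14 falls adjusted over the list alone (camera, adjusted p = 0.000142, and adjusted p = 0.288 with an estimated correlation). The phosphatase DUSP4 (−4.94 ± 0.170), the feedback inhibitors SPRY1 (−2.92 ± 0.0824) and SPRED2 (−1.57 ± 0.0871) and the transcription factor ETV5 (−1.97 ± 0.0937) fell. Against the name of the list, IER3 (1.37 ± 0.0887), the proliferation factor MYC (1.5 ± 0.160) and EPHA2 (0.39 ± 0.138) rose, and these were singled out after their values were seen. EPHA2 did not pass without line A replicate 1 or 2, line B replicate 2 or feeder-free replicate 1 or 2 (adjusted p = 0.0630 to 0.103). Nodal and Activin targets were higher, with 9 of 12 rising, 1 falling and 2 not passing, as they were adjusted over the list alone (camera, adjusted p = 0.00335, and adjusted p = 0.114 with an estimated correlation). The feedback regulators PMEPA1, SMAD7 and SKIL rose by 2.89 ± 0.120, 2.48 ± 0.105 and 1.89 ± 0.112.

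LIF and STAT3 targets, of which 9 of 16 rose, 3 fell and 4 did not pass (9 and 3 adjusted over the list alone), were not called as a list (camera, adjusted p = 0.275, and adjusted p = 0.583 with an estimated correlation). SOCS3, the feedback inhibitor of the pathway, rose by 1.07 ± 0.121. GADD45G (−3.07 ± 0.253) fell, as did the kinases PIM1 (−0.45 ± 0.148) and PIM3 (−0.44 ± 0.0624), both named after their values were seen. PIM1 did not pass without line A replicate 2, line B replicate 1 or either MEF library (adjusted p = 0.0716 to 0.0770). Among 9 WNT and beta-catenin targets, 5 fell, 1 rose and 3 did not pass, or 5 and 2 adjusted over the list alone (camera, adjusted p = 0.117, and adjusted p = 0.295 with an estimated correlation). SP5 (−2.22 ± 0.237), BAMBI (−1.62 ± 0.189) and AXIN2 (−1.22 ± 0.172), a negative regulator of the pathway, fell. LEF1 (−0.98 ± 0.175) and ZNRF3 (−0.41 ± 0.10), named after their values were seen, fell too, and TCF7 rose by 0.69 ± 0.119.

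Epithelial genes were higher in naive-like cells, with 15 of 19 rising and 4 falling, as they were adjusted over the list alone (camera, adjusted p = 0.000846, and adjusted p = 0.0900 with an estimated correlation). The adhesion molecule EPCAM rose by 3.30 ± 0.102, from 39.1 ± 5.25 to 393 ± 33.7 TPM, the cadherin CDH3 by 2.79 ± 0.0916 and the splicing regulator ESRP1 by 4.59 ± 0.0990. The simple keratins KRT8 (−4.22 ± 0.142) and KRT18 (−2.21 ± 0.0735) fell. TJP1 (−0.33 ± 0.0824) and CLDN4 (−0.62 ± 0.224), singled out after their values were seen, fell too. CLDN4 did not pass without line A replicate 1 or 2, line B replicate 2 or feeder-free replicate 1 or 2 (adjusted p = 0.0849 to 0.112). Mesenchymal genes were lower, with 5 of 11 falling, 1 rising and 5 not passing, as they were adjusted over the list alone (camera, adjusted p = 0.0133, and adjusted p = 0.424 with an estimated correlation). VIM, an intermediate filament, fell by 3.16 ± 0.265, from 1703 ± 106 to 203 ± 87.0 TPM, and ZEB1 (−2.09 ± 0.140) and ITGA5 (−1.72 ± 0.0831) fell along with CDH2. ZEB2 (−2.67 ± 0.241) and SNAI1, a repressor of CDH1 that rose by 1.15 ± 0.0991, were named after their values were seen.

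Among lineage groups, neuroectoderm genes were lower, with 12 of 14 falling and 2 not passing, or 13 falling adjusted over the list alone (camera, adjusted p = 1.29e-07, and adjusted p = 0.0900 with an estimated correlation). SOX1 (−3.32 ± 0.176) and RAX (−2.88 ± 0.110) fell, with means of 9.88 and 7.29 TPM in primed cells, along with LHX2. Hypoblast genes were lower too, with 9 of 12 falling, 1 rising and 2 not passing, or 10 and 1 adjusted over the list alone (camera, adjusted p = 0.000702, and adjusted p = 0.163 with an estimated correlation). The apolipoprotein APOA1 fell by 2.39 ± 0.0982, from 412 ± 43.3 to 77.9 ± 9.61 TPM, and LAMA1 (−1.96 ± 0.148) and SPARC (−1.11 ± 0.0701) fell too, while LAMB1 rose by 0.65 ± 0.0642. In the primitive streak and definitive endoderm list, 2 of 5 rose, 2 fell and 1 did not pass, as they did adjusted over the list alone (camera, adjusted p = 0.535, and adjusted p = 0.623 with an estimated correlation). GSC and EOMES rose, CXCR4 fell by 1.20 ± 0.150, and FOXA2 was at 0.890 to 1.92 TPM in primed libraries against 0.165 to 0.239 TPM in 3 naive-like libraries and 0 in MEF replicate 2. Trophectoderm genes split into 3 rises and 4 falls among 8, as they did adjusted over the list alone (camera, adjusted p = 0.256, and adjusted p = 0.424 with an estimated correlation). KRT19 rose by 1.26 ± 0.0838 and TEAD4 fell by 2.90 ± 0.116 along with KRT8 and KRT18. VGLL1 (2.29 ± 0.298) rose and ELF5 (−1.18 ± 0.201) fell, and both were named after their values were seen.

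Glycolysis genes were lower in naive-like cells, with 18 of 20 falling and 2 not passing, or 19 falling adjusted over the list alone (camera, adjusted p = 4.83e-09, and adjusted p = 0.288 with an estimated correlation). The glucose transporter SLC2A3 fell by 3.12 ± 0.163, from 1349 ± 215 to 155 ± 34.99 TPM. PDK1 (−3.70 ± 0.141), which restrains entry of pyruvate into the citric acid cycle, PGAM1 (−1.08 ± 0.0545) and hexokinase HK2 (−1.66 ± 0.129) fell as well. Hypoxia targets, which share PDK1 and SLC2A1 with that list, were lower as well, with 12 of 15 falling and 3 not passing, or 12 falling and 1 rising adjusted over the list alone (camera, adjusted p = 2.88e-05, and adjusted p = 0.163 with an estimated correlation). BNIP3 (−3.49 ± 0.177) and P4HA1 (−1.62 ± 0.0985) fell, and ANKRD37 was at 8.41 to 15.8 TPM in primed libraries against 0.182 and 0.211 TPM in the first and 0 in the second replicate of each naive-like group. YAP and TEAD targets were lower, with 6 of 15 falling and 9 not passing, as they were adjusted over the list alone (camera, adjusted p = 0.0263, and adjusted p = 0.343 with an estimated correlation). ANKRD1 (−3.07 ± 0.170), AXL (−1.78 ± 0.109), PTPN14 (−1.42 ± 0.111) and CCN1 (−0.70 ± 0.138) fell. Targets of p53 were higher, with 9 of 14 rising, 2 falling and 3 not passing, as they were adjusted over the list alone (camera, adjusted p = 0.0193, and adjusted p = 0.583 with an estimated correlation). PMAIP1, a BH3-only regulator of apoptosis, rose by 1.46 ± 0.211, TP53I3 by 1.17 ± 0.141, AEN by 0.70 ± 0.0796 and CCNG1 by 0.68 ± 0.0619. BBC3 (−0.53 ± 0.112), also a BH3-only regulator, and ZMAT3 (−0.69 ± 0.174), both named after their values were seen, fell.

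**Figure D3:**
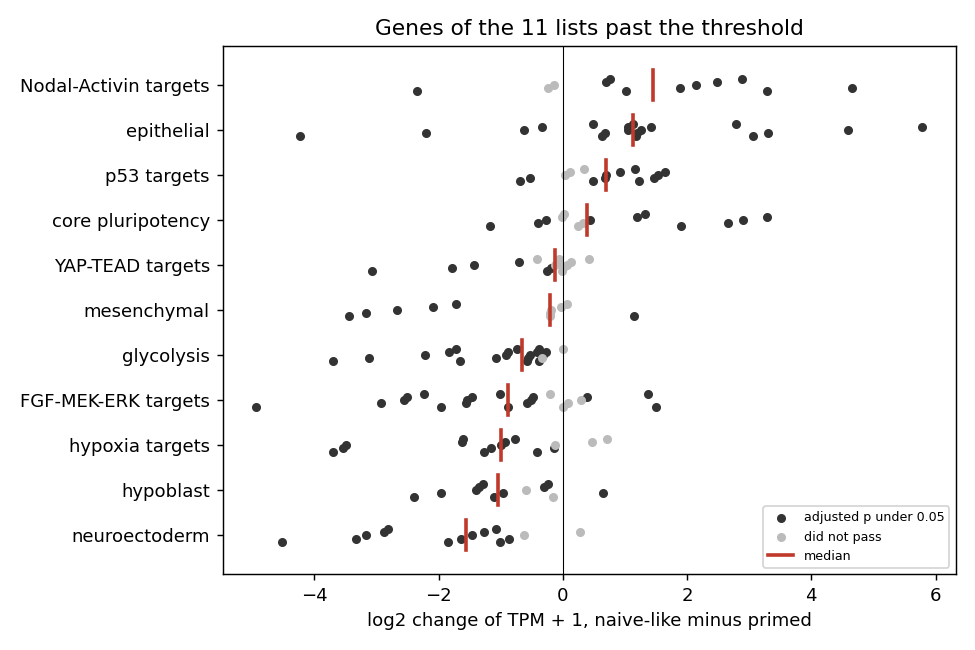
Log2 change of each tested member of 11 gene lists, naive-like minus primed, with points for genes and a line for the median of each list. Glycolysis and neuroectoderm members lie mostly below 0, and epithelial members lie mostly above 0.

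The feeder-free naive-like libraries were compared with the 4 primed libraries, which were feeder-free too, so that no MEFs were in either arm. CYP1A1 was at 787 ± 31.1 TPM (n = 2) in feeder-free naive-like cells, a rise of 7.85 ± 0.0857, and CLDN7 at 295 ± 12.2 TPM, a rise of 5.92 ± 0.208. COL4A4 (5.47 ± 0.113), GSC (5.18 ± 0.148), CLIC6 (4.78 ± 0.116) and COL4A3 (4.39 ± 0.129) rose too, as did NODAL. SFRP2, a secreted modulator of WNT signalling, fell by 4.98 ± 0.142, from 262 ± 69.1 to 7.26 ± 2.40 TPM. The gap junction protein GJA1 (−4.94 ± 0.118), DLK1 (−5.42 ± 0.132), CNTFR (−5.40 ± 0.111) and the cytoskeletal linker MSN (−4.72 ± 0.148) fell, along with CAPN6 and NDN. Of the 14779 genes, 4550 rose and 3781 fell, 8331 in all, and changes of at least 2-fold numbered 739 and 1043. With median-ratio scaling 4020 rose and 4364 fell, 3931 and 4253 after rescaling without ribosomal RNA genes (chosen after seeing the data) and 3560 and 3626 without feeder-free replicate 1, so the balance of directions depends on these choices.

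Gene lists were tested for this comparison after the data were seen. Cholesterol synthesis genes were higher in feeder-free naive-like than in primed cells, with 14 of 19 rising and 5 not passing, as they were adjusted over the list alone (camera, adjusted p = 0.000485, and adjusted p = 0.340 with an estimated correlation). FDPS rose by 0.77 ± 0.0403, NSDHL by 0.81 ± 0.0513, IDI1 by 0.62 ± 0.0465 and MVD by 0.46 ± 0.0420. Fibroblast genes were lower, with 14 of 20 falling, 1 rising and 5 not passing, as they were adjusted over the list alone (camera, adjusted p = 5.82e-05, and adjusted p = 0.196 with an estimated correlation). PDGFRB (−2.90 ± 0.137), ACTA2 (−1.90 ± 0.0642), COL1A2 (−1.60 ± 0.111) and TAGLN (−0.99 ± 0.0366) fell, while COL5A1, a collagen named after its values were seen, rose by 0.21 ± 0.0750. COL5A1 did not pass without line A replicate 2, line B replicate 2 or any 1 of the 4 naive-like libraries (adjusted p = 0.0674 to 0.177). Of the 11 lists called for state, 10 were called here in the same direction (camera, adjusted p = 2.50e-10 to 0.0238, and adjusted p = 0.0919 to 0.267 with an estimated correlation), and the YAP and TEAD list was not (0.0554). Both comparisons used the same primed and feeder-free naive-like libraries, so the shared direction is no separate evidence.

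The comparison of naive-like cells on MEFs with feeder-free naive-like cells asked what differed with the feeder layer. COL1A2 was at 38.0 ± 1.42 TPM (n = 2) on MEFs against 0.133 ± 0.122 TPM (n = 2), COL3A1 at 18.7 ± 1.67 against 0.103 ± 0.0295 TPM and the matrix proteoglycan BGN at 128 ± 5.12 against 2.33 ± 0.625 TPM. The ERK phosphatase DUSP6 was lower, at 11.1 ± 0.540 against 28.8 ± 1.29 TPM. In limma, 762 of 14779 genes passed, 427 higher and 335 lower on MEFs, and changes of at least 2-fold numbered 132 and 21. Among genes with a mean of at least 5 TPM, 327 were higher and 333 lower. Among genes with a mean of at least 5 TPM, a gene symbol and no overlap, rises were 5.28 ± 0.194 in BGN, 5.11 ± 0.128 in COL1A2, 4.15 ± 0.151 in COL3A1, 3.88 ± 0.163 in SFRP2 and 2.84 ± 0.176 in WLS. CDH11 (2.76 ± 0.102), COL1A1 (2.42 ± 0.0962), TIMP2 (2.40 ± 0.0894) and FOXB2 (2.28 ± 0.126) followed. Falls under the same limits were in ANXA1 (−1.45 ± 0.161), DUSP6 (−1.29 ± 0.0721), LPAR6 (−1.26 ± 0.208), TNFSF9 (−1.20 ± 0.142), CIB3 (−1.17 ± 0.184), ERAP2 (−1.10 ± 0.153), TM7SF2 (−1.02 ± 0.0645), ALDH18A1 (−0.99 ± 0.0778), MAP7D3 (−0.97 ± 0.0640) and PERP (−0.96 ± 0.0674). POU5F1 (−0.13 ± 0.0420), NANOG (−0.43 ± 0.206) and SOX2 (0.05 ± 0.0548) did not pass, and in limma 0 of the 14 core pluripotency genes tested did, with 5 at an unadjusted p under 0.05. Adjusted over the list alone 1 fell, UTF1 (−0.33 ± 0.0805; camera for the list, adjusted p = 0.570, and adjusted p = 0.786 with an estimated correlation). Leaving out any 1 of the 4 naive-like libraries lowered the count and raised the share of rises among the genes that passed. The balance of directions thus depends on how many libraries were used, and its shift does not come from 1 particular library. LPAR6 did not pass without either feeder-free library (adjusted p = 0.0576 to 0.0636), and CIB3 did not pass without either feeder-free library or MEF replicate 2 (0.05003 to 0.0708).

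Fibroblast genes, the list fixed for feeder RNA, were higher on MEFs: 9 of 20 rose, 3 fell and 8 did not pass, or 14 and 3 adjusted over the list alone (camera, adjusted p = 1.30e-09, and adjusted p = 0.170 with an estimated correlation). COL1A1 was at 156 ± 1.76 TPM against 28.3 ± 0.382 TPM. LUM (−0.59 ± 0.106), TAGLN (−0.22 ± 0.0423) and COL5A1 (−0.41 ± 0.0866), named after their values were seen, fell. Mesenchymal genes were higher too, with 5 of 11 rising and 6 not passing, or 8 rising and 1 falling adjusted over the list alone (camera, adjusted p = 4.5e-05, and adjusted p = 0.170 with an estimated correlation). VIM rose by 1.11 ± 0.0516 to 278 ± 10.3 TPM, ZEB2 by 0.94 ± 0.124, CDH2 by 0.62 ± 0.0745 and MMP14, named after its values were seen, by 0.44 ± 0.0884. TWIST1 was at 2.28 and 1.75 TPM on MEFs, was listed at 0 in feeder-free replicate 1 and was at 0.283 TPM in feeder-free replicate 2. In the neuroectoderm list 3 of 14 rose and 11 did not pass, or 4 rising adjusted over the list alone (camera, adjusted p = 0.00466, and adjusted p = 0.170 with an estimated correlation), with SIX3 up by 1.95 ± 0.124, STMN2 by 0.96 ± 0.0491 and ELAVL3 by 0.58 ± 0.120. Without MEF replicate 1, the adjusted p of TWIST1 was 0.0635. Leaving out any 1 of the 4 naive-like libraries ended the calls of TAGLN (0.0789 to 0.181), MMP14 (0.0911 to 0.171), COL5A1 (0.0574 to 0.192, also without either line B library) and ELAVL3 (0.0540 to 0.196, also without either line A library). LUM did not pass without feeder-free replicate 1 or either MEF library (0.0521 to 0.140).

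Cholesterol synthesis genes were lower on MEFs, with 16 of 19 falling and 3 not passing, as they were adjusted over the list alone (camera, adjusted p = 1.77e-23, and adjusted p = 0.170 with an estimated correlation). FDPS fell by 0.76 ± 0.0466, from 837 ± 17.03 to 496 ± 16.1 TPM. MSMO1 (−0.82 ± 0.0469), SQLE (−0.75 ± 0.0536), an early enzyme of the sterol branch, and MVD (−0.73 ± 0.0485) fell too. The list mean of log2(TPM + 1) was 7.20 and 7.11 in feeder-free, 6.59 and 6.58 in MEF, 6.82 and 6.74 in line A and 6.80 and 6.72 in line B libraries. The share of ribosomal RNA genes in TPM was 3.09 ± 0.559% on MEFs and 1.53 ± 0.141% feeder-free.

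On MEFs, targets of FGF, MEK and ERK signalling were lower, with 5 of 21 falling and 16 not passing, or 10 falling adjusted over the list alone (camera, adjusted p = 1.03e-05, and adjusted p = 0.220 with an estimated correlation). Beside DUSP6, MYC (−0.58 ± 0.0768), SPRY4 (−0.61 ± 0.0949), ETV4 (−0.56 ± 0.0936) and DUSP4 (−0.50 ± 0.0965), which was named after its values were seen, fell. Targets of p53 were lower as well, with 5 of 14 falling and 9 not passing, or 9 falling adjusted over the list alone (camera, adjusted p = 3.22e-07, and adjusted p = 0.171 with an estimated correlation). PHLDA3 (−0.89 ± 0.0980), the cell cycle inhibitor CDKN1A (−0.90 ± 0.135), the apoptosis effector BAX (−0.53 ± 0.0853), TP53INP1 (−0.39 ± 0.0754) and TP53I3 (−0.52 ± 0.10), which was named after its values were seen, fell. In the interferon and antiviral list 1 of 13, B2M (−0.94 ± 0.0780), fell and 12 did not pass, and the count was the same adjusted over the list alone (camera, adjusted p = 0.0138, adjusted p = 0.382 with an estimated correlation, and 0.0934 with fry). Nuclear genes of oxidative phosphorylation were called lower as a list (camera, adjusted p = 0.0207, and adjusted p = 0.206 with an estimated correlation) while 0 of 20 passed alone in limma, as 0 did adjusted over the list alone, and 3 had an unadjusted p under 0.05. That list call ended without feeder-free replicate 2 (0.373) or MEF replicate 2 (0.0511), with quantile normalization (0.592), without the variance trend (0.0710) and after rescaling without ribosomal RNA genes (0.0657). Without either MEF library, MYC (0.0617 to 0.0649) and CDKN1A (0.0657 to 0.0804) did not pass. Without either of these or feeder-free replicate 2, SPRY4 (0.0502 to 0.0804), ETV4 (0.0734 to 0.1205) and BAX (0.0661 to 0.103) did not pass. TP53INP1 did not pass without feeder-free replicate 1 or either MEF library (0.0691 to 0.169), TP53I3 without any 1 of the 4 naive-like libraries (0.0777 to 0.186) and DUSP4 without any 1 of the 8 libraries (0.0506 to 0.140).

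**Figure D4:**
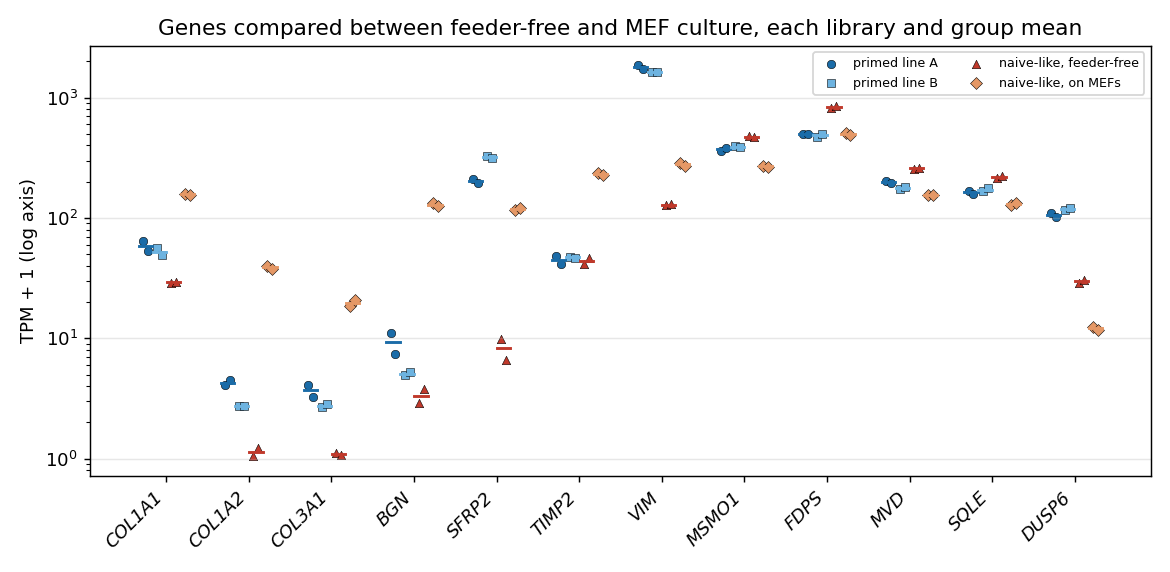
TPM + 1 of 12 fibroblast, cholesterol synthesis and ERK target genes in each library on a log axis, with points for libraries and bars for the mean of each group. COL1A2 and COL3A1 lie higher on MEFs than in feeder-free naive-like libraries, and FDPS and DUSP6 lie lower.

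The comparison of the 2 primed lines asked how far cells of the same state and medium differed between lines. NES, an intermediate filament of neural progenitors, was at 13.7 ± 1.33 TPM (n = 2) in line B and at 70.6 ± 5.65 TPM (n = 2) in line A, and BHMT, an enzyme of methionine synthesis, at 1.604 ± 0.211 against 33.7 ± 0.807 TPM. LDOC1 was at 27.9 and 27.2 TPM in line B and 0.662 and 0.689 TPM in line A, and was listed at 0 in MEF replicate 2. ZNF532 was at 42.3 ± 1.22 TPM in line B against 4.89 ± 0.367 TPM in line A. In limma, 1087 of 14779 genes passed, 618 higher and 469 lower in line B, with 113 and 141 at least 2-fold. Of those passing, 56.9% were higher in line B, against 39.5% with median-ratio scaling and 43.7% with quantile normalization, so the balance of directions depends on scaling. The count was 353 without line A replicate 1 (182 higher and 171 lower), 480 without line A replicate 2 (231 and 249), 446 without line B replicate 1 (209 and 237) and 427 without line B replicate 2 (209 and 218).

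ZNF532 rose by 2.88 ± 0.114 in line B, TAFAZZIN by 2.55 ± 0.151, OVAR by 1.71 ± 0.176, CCT6A by 1.64 ± 0.0510 and NEGR1 by 1.49 ± 0.134. GSDME (1.33 ± 0.0863), EID1 (1.32 ± 0.0689) and ICE2 (1.23 ± 0.165) rose too. RPL37A, a ribosomal protein gene, was at 1625 ± 13.9 TPM in line B and 260 ± 18.3 TPM in line A. Whether reads of this gene are shared with close copies was not examined here. Among genes with a mean of at least 5 TPM, a gene symbol and no overlap, falls were in BHMT (−3.74 ± 0.115), PLAAT1 (−2.59 ± 0.193), NES (−2.29 ± 0.0969), BPIFB3 (−2.03 ± 0.161) and ACAA2 (−1.996 ± 0.159). MIEN1 (−1.89 ± 0.201), TAL1 (−1.87 ± 0.142), NUDT16 (−1.85 ± 0.0706), B3GNT7 (−1.79 ± 0.155) and MSN (−1.63 ± 0.171) fell too. POU5F1 (−0.08 ± 0.0420), NANOG (0.39 ± 0.206) and SOX2 (0.14 ± 0.0548) did not pass. SALL4 rose by 0.36 ± 0.0598, DPPA2 fell by 1.37 ± 0.204 and GBX2 rose by 1.14 ± 0.166. ICE2 did not pass without line A replicate 1 (adjusted p = 0.0506), and DPPA2 did not pass without line A replicate 1 or line B replicate 2 (0.0568 to 0.0658). SALL4 did not pass without either line A library or line B replicate 2 (0.0671 to 0.0732).

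Glycolysis genes were lower in line B, with 10 of 20 falling and 10 not passing, or 17 falling adjusted over the list alone (camera, adjusted p = 2.12e-13, and adjusted p = 0.290 with an estimated correlation). ENO1 (−0.41 ± 0.0505), GPI (−0.37 ± 0.0447) and HK2 (−0.49 ± 0.0790) fell, as did GAPDH (−0.38 ± 0.0554), from 4096 ± 238 TPM in line A to 3153 ± 167 TPM in line B. Hypoxia targets were lower too, with 6 of 15 falling and 9 not passing, or 7 falling adjusted over the list alone (camera, adjusted p = 0.000234, and adjusted p = 0.377 with an estimated correlation). BNIP3 (−0.70 ± 0.0932), ADM (−0.95 ± 0.153), P4HA2 (−0.73 ± 0.153) and the angiogenic factor VEGFA (−0.91 ± 0.157) fell. In the fibroblast list ACTA2 rose by 0.55 ± 0.0742, COL1A2 (−0.64 ± 0.128) and BGN (−0.84 ± 0.194) fell and 17 of 20 did not pass, or 2 rose and 5 fell adjusted over the list alone (camera, adjusted p = 0.0269, and adjusted p = 0.786 with an estimated correlation). That list call ended without line A replicate 1 (0.0670) or line B replicate 2 (0.105), with a pseudocount of 0.1 (0.0542), median-ratio scaling (0.0547), quantile normalization (0.0661) and fry (0.189). The share of ribosomal RNA genes in TPM was 4.77 ± 0.499% in line B and 6.08 ± 0.258% in line A. Without line A replicate 1, GAPDH (0.0506) and BNIP3 (0.0502) did not pass, and HK2 (0.0607 to 0.0697) and ADM (0.0510 to 0.0680) did not pass without any 1 of the 4 primed libraries. COL1A2 did not pass without any 1 of the 4 primed or 2 MEF libraries (0.0586 to 0.122). BGN (0.0776 to 0.179) and P4HA2 (0.0535 to 0.166) did not pass without line A replicate 1 or any line B or MEF library, and VEGFA did not without line A replicate 2 or line B replicate 2 (0.0850 to 0.0918).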

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

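Tests of mesenchymal genes as a sign of feeder RNA, of dilution and of CYP1A1 as feeder RNA were chosen only after the results they measure were seen, and rescaling without ribosomal RNA genes was chosen after seeing the data.

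State separated 7493 genes. Of the 35 splits of the 8 libraries into 4 and 4, 1 gave as many, the real split. The highest of the others gave 2, but each of these mixes both states on each side. The state difference then adds to the spread within each side, which keeps their calls low. A share of 1 in 35 is the lowest these splits can give, and it counts only if the 8 libraries are independent. Only 3 splits kept the 2 libraries of each group together, too few for a share under 0.05, so the splits do not exclude chance. After rescaling without ribosomal RNA genes, at 1.43 to 3.48% of TPM in naive-like and 4.42 to 6.26% in primed libraries, 7417 passed, of which 7033 were among the 7493, which argues against that share as the source of the calls, though the balance moved from 4233 rises and 3260 falls to 3776 and 3641. Passage, medium and state changed together, so their parts stay open, and the biological difference in state was not tested apart from them.

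Fibroblast genes were higher on MEFs, with 9 of 20 rising, 3 falling and a median log2 change of 0.59 (camera, adjusted p = 1.30e-09, and adjusted p = 0.170 with an estimated correlation). RNA from feeder cells would bring mesenchymal genes too, and the 10 outside the fibroblast list had a median of 0.46 (0.4628), between the bounds set for and against it, so it cannot be told apart from an untested response of the naive-like cells to the feeder layer, which the design names. TAGLN, the most abundant of the fibroblast list, was at 425 ± 2.68 TPM on MEFs against 494 ± 3.85 TPM feeder-free. Which species the transcripts came from cannot be read from TPM, and no step that removes feeders is given in the sources used here. Dilution by such RNA would lower alike all genes that feeders do not express, but the 14 core pluripotency genes had a median of 0.02 (0.0202, SD 0.275). The 335 called falls had a median of −0.51, but they were picked for falling, so part of that gap is built in. CRIPTO, which the core list held under an older name and is not among the 14, was lower by 0.90. The core median still argues against dilution as the source of the falls as a whole.

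CYP1A1 was higher in naive-like cells. In feeder-free naive-like cells, grown without feeders, it rose by 7.85 (7.8515), which argues against that source. A general response of the aryl hydrocarbon receptor predicts that its other targets rise. Of the 7 names on the list of targets, only 4 were tested, and their median was 2.35 (2.3453). AHRR, NQO1 and TIPARP rose and NFE2L2 did not pass (−0.04, adjusted p = 0.797). A receptor response may therefore be at work, as a hypothesis, and whether a compound of the medium starts it was not tested.

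Single libraries stood apart from the other 3 of their state in 16 of 453 groups by the Dixon test, where chance flags about 1 in 20 groups. In feeder-free replicate 1, AP1M2 was at 30.7 TPM (35.1 to 35.9 in the others), ESRP1 at 62.0 (54.7 to 55.2), TCF7L1 at 127 (121 to 122), ITGA5 at 8.07 (6.73 to 6.91), COL4A3 at 24.9 (18.5 to 19.04), ZNRF3 at 4.53 (3.91 to 4.01) and the mean of the YAP and TEAD list at 4.02 (3.90 to 3.92). Feeder-free replicate 2 had TRIM28 at 514 TPM (478 to 482), TET1 at 19.02 (24.8 to 25.1) and the mean of the DNA methylation list at 4.80 (4.95 to 4.97). In MEF replicate 1, GBX2 was at 0.0384 TPM (0 in the others), ANKRD1 at 0.173 (0.822 to 0.957) and PCNA at 601 (615 to 618). Line A replicate 2 had CD24 at 219.6 TPM (229 to 230.3) and MAP7D3 at 23.0 (24.6 to 24.9), and line B replicate 1 had FDPS at 472 TPM (494 to 498).

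With the same primed libraries in both arms, a difference in the change with state between MEF and feeder-free libraries equals the comparison of MEFs with feeder-free cells, and is no further finding. By that comparison (limma, MEF minus feeder-free) it differed in 8 lists: fibroblast by 1.33, mesenchymal by 0.51, neuroectoderm by 0.34, oxidative phosphorylation by −0.07, interferon by −0.24, FGF-MEK-ERK by −0.29, p53 by −0.39 and cholesterol synthesis by −0.57. With an estimated correlation 0 of these were called in camera (adjusted p = 0.170 to 0.382), and the interferon and oxidative phosphorylation calls also ended under other alternatives. Of 131 named genes, 23 differed (largest adjusted p = 0.0499). The log2 change (naive-like minus primed, with its sign) was higher on MEFs in VIM (1.11), GADD45G (0.95), ZEB2 (0.94), CAPN6 (0.74), PEG10 (0.74), CDH2 (0.62), NDN (0.57), UHRF1 (0.29) and OTX2 (0.24). It was lower on MEFs in TAGLN (−0.22), DUSP4 (−0.50), CYP1A1 (−0.51), CCN1 (−0.51), TP53I3 (−0.52), SLC2A3 (−0.54), OLFML3 (−0.57), MYC (−0.58), CLIC6 (−0.65), FDPS (−0.76), NODAL (−0.79), CRIPTO (−0.90), VGLL1 (−1.15) and DUSP6 (−1.29).

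With the same naive-like libraries in both arms, the change with state against line A minus that against line B equals the comparison of line B with line A. It differed in 3 lists, fibroblast by −0.12, glycolysis by −0.29 and hypoxia by −0.34. With an estimated correlation 0 of these were called in camera (adjusted p = 0.290 to 0.786), and the fibroblast call also ended with fry (0.189) and other alternatives. The change differed in 15 of the 131 genes (largest adjusted p = 0.0440), namely GBX2 (1.14), NDN (0.83), CRIPTO (0.73), SOX1 (0.65), DUSP4 (0.44), OLFML3 (0.39), SALL4 (0.36), SOCS3 (0.34), KRT18 (−0.25), SLC2A3 (−0.40), HK2 (−0.49), KRT8 (−0.51), ANKRD37 (−0.68), BNIP3 (−0.70) and DPPA2 (−1.37).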

How the results depend on the processing

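Rescaling without ribosomal RNA genes and the lists for feeder-free naive-like against primed cells were chosen after seeing the data, and the other alternatives were planned. For 239 named gene results, 5383 alternative values were computed. Of these, 5087 kept the direction and the side of the threshold, 270 no longer passed, 9 newly passed and 17 reversed, and 185 of the results kept both under every alternative run. Among 34 list calls, 711 of 757 alternative values kept both and 46 no longer passed, of which 34 came with an estimated correlation. The cause was not tested unless it follows from how an alternative is built, as with stricter thresholds or fewer libraries. What depth limits cannot be said, because TPM hold no counts.

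State gave 7493 genes, 1595 at 2-fold or more, 4023 with means of subgroups and 5848 with the subgroup as a random block. Of 131 named genes for state, 15 no longer passed with means of subgroups and 6 with the subgroup as a random block. Leaving out 1 library gave 6723 to 7101 genes for state and 7022 to 7897 for feeder-free naive-like against primed cells, which gave 8331 and, at 2-fold or more, 1782. MEFs against feeder-free gave 762, and 497 with no filter, 153 at 2-fold or more, 253 at an adjusted p under 0.01, 235 with the groups compared alone and 191 to 610 without 1 library. The primed lines gave 1087, and 254 at 2-fold or more, 364 at an adjusted p under 0.01, 420 with the groups compared alone and 353 to 1213 without 1 library. List calls numbered 11, 12, 8 and 3 for state, feeder-free against primed, MEFs and lines, 0 in each with an estimated correlation in limma's camera (6, 6, 6 and 2 at an unadjusted p under 0.05), and 23, 23, 10 and 4 with fry. Without 1 library they were 11 to 12, 12 to 13, 7 to 8 and 2 to 3. Replicate number as a block gave 7237, 8407, 697 and 1050 genes and 11, 13, 8 and 3 lists. Deviations of equally numbered replicates correlated across genes at −0.0748 to 0.0973, which gives no sign that the numbers pair the libraries but does not exclude it.

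Reversed values were near 0 and not past the threshold. SOX2 for state (0.02; −0.0043 to 0.0549 without 1 library) went to −0.0397 with median-ratio scaling, −0.0184 with quantile normalization, −0.0229 without ribosomal RNA genes, −0.0043 without line A replicate 1 and −0.0459 with line B only. For MEFs (0.05; −0.0237 to 0.1168) it went to −0.0237 without feeder-free replicate 2. UTF1 for state (−0.0056; −0.0930 to 0.0519 without 1 library) went to 0.0031 without ribosomal protein genes, 0.0385 and 0.0188 without line A replicates 1 and 2, 0.0475 and 0.0519 without MEF replicates 1 and 2, 0.0970 with line B only and 0.1603 with feeder-free cells only. NFE2L2 for state (−0.0392; −0.1181 to 0.0352) went to 0.0352 and 0.0096 without line B replicates 1 and 2, 0.01 without feeder-free replicate 2 and 0.1455 with line A only.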

Other observations

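The test of a primed fraction in cultures on MEFs was chosen only after its result was seen, as were the genes named here outside the rule.

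Imprinted genes went both ways with state, with 6 of 17 rising, 9 falling and 2 not passing, as they did adjusted over the list alone (camera, adjusted p = 0.117, and adjusted p = 0.450 with an estimated correlation). Beside DLK1, the growth factor IGF2 fell by 2.64 ± 0.177, from 7.57 ± 1.80 to 0.365 ± 0.215 TPM, and MEST (−2.32 ± 0.0963) and PEG10 (−1.88 ± 0.197) fell too, the latter from 201 ± 15.5 to 56.0 ± 17.1 TPM. Of 12 genes of the DNA methylation machinery, 4 rose, 4 fell and 4 did not pass, or 4 and 5 adjusted over the list alone (camera, adjusted p = 0.888, and adjusted p = 0.937 with an estimated correlation), and the median (0.03) and mean (0.05) of the list were above 0 while camera put it lower. DNMT3B rose by 2.05 ± 0.0698 and TRIM28, a corepressor at imprinted loci, by 0.48 ± 0.0456, while DNMT3A (−1.15 ± 0.0832) and TET2 (−1.11 ± 0.154), which oxidises methylcytosine, fell. UHRF1 (0.29 ± 0.0851), GADD45B (0.59 ± 0.171), TET1 (−0.28 ± 0.0957) and TET3 (−0.26 ± 0.0846) were named after their values were seen. GADD45B did not pass without feeder-free replicate 1 (adjusted p = 0.0508), TET1 without any 1 of the 4 primed libraries (0.0518 to 0.0890) and TET3 without replicate 1 of either line or either feeder-free library (0.0537 to 0.0707).

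Targets of the aryl hydrocarbon receptor were measured beside CYP1A1. AHRR, the repressor of the receptor, rose by 3.01 ± 0.119, from 2.00 ± 0.408 to 23.1 ± 2.26 TPM (n = 4 and 4), the quinone reductase NQO1 by 3.03 ± 0.181, from 5.08 ± 1.36 to 48.5 ± 9.12 TPM, and TIPARP by 1.68 ± 0.0694, from 14.3 ± 0.785 to 47.9 ± 3.27 TPM. NFE2L2 was at 25.5 ± 2.28 against 26.4 ± 4.14 TPM. CRIPTO, a co-receptor of Nodal that the core list held under an older name, fell by 0.91 ± 0.284, and it was at 5.52 and 5.86 TPM in line A, 9.77 and 10.4 in line B, 4.83 and 5.75 in feeder-free and 2.60 and 2.14 in MEF libraries. CRIPTO did not pass without either line B or either MEF library (adjusted p = 0.0609 to 0.0652). FDPS was at 490 ± 11.5 TPM in primed cells, at 496 ± 16.1 TPM on MEFs and at 837 ± 17.03 TPM in feeder-free naive-like cells, and the state comparison gave 0.40 ± 0.180 (adjusted p = 0.0956).

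Some genes of primed cells were higher on MEFs than in feeder-free naive-like cells. A fraction of primed cells in these cultures would regain a like percent of the primed level in each gene of those cells. Over 110 genes the median regained was 3.12%, and no single percent lay within 2 SE of more than 37 of them, or of more than 18 of the 40 called higher on MEFs. SFRP2 regained 43.6%, CDH11 37.4%, FOXB2 26.9%, VIM 9.54%, CNTFR 0.235%, DLK1 −0.00371% and SLC2A3, at 1349 TPM in primed cells, −4.99%. These values argue against such a fraction as the source of the whole pattern, while a small fraction, feeder RNA and a response to feeders stay open.

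The line from which the naive-like cells came was tested at the 254 genes that differed at least 2-fold between the primed lines. At 161 of them the naive-like mean was nearer to line A, 63.4% (63.39; Wilson 95% interval 57.3 to 69.1%). This spans the limit of 65% set for no preference and lies below the 75% set for a preference, so origin in line A cannot be told apart from no preference. Genes are not independent, and the interval covers counting error alone.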
